A study of Mus musculus with 20 samples.

How the data were processed

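Total RNA from the liver of male BALB/c mice, 6 weeks old on arrival, was hybridised to Affymetrix mouse arrays, with 1 array per mouse. Per the labels, diabetes was induced by 1 intraperitoneal injection of streptozotocin at 185 mg/kg, and untreated mice received no injection. The study had 6 mice per group, of which 5 per group had an array. Diabetic mice were fed a plain AIN93G diet or this diet with 0.1% or 0.5% phloridzin for 14 days, and the mice were killed under anaesthesia.

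The values deposited by the authors were intensity values, a linear signal for each probe set, already scaled so that the mean after dropping the lowest and highest 2% of probe sets was 100 on each array. The software that made them is not given in the sources used here. Of 45101 probe sets, 64 were controls, 9160 had no listed gene and 932 had several genes, and these were left out of the comparisons. The other 34945 named 18193 genes. The Entrez identifiers of 34741 of them were found in the reference gene table, and 0 symbols changed.

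Values were taken as log2 of the signal plus 16. For a gene with several probe sets, the one with the highest mean over the 20 arrays was used, and genes with a mean at or above the 40th percentile of probe sets (a signal of about 8.48) were kept, 12947 in all. A model of 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with default settings), two-sided, with 16 residual degrees of freedom and 4.56 from the prior. Adjusted p were by Benjamini and Hochberg over all genes kept, and a gene was called at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9.

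The 6 comparisons were STZ against untreated, each phloridzin group against STZ, the 2 phloridzin groups against each other, and each phloridzin group against untreated. In the first 4, limma camera with a preset correlation of 0.01 was run on 39 gene lists with at least 5 measured genes, out of 29 pathway lists and 13 cell type lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way and does not compare them with other genes, were run beside it. Lists with a median, mean and camera direction of unlike sign are named as such where they are described.

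For the reversal of the STZ response, the 5 STZ arrays were split into disjoint parts of 2 and 3 in 20 ways, 1 part for the STZ effect and the other for the phloridzin effect. The value is the mean over splits of the median phloridzin change, turned by the sign of the STZ change. An exact permutation test compared 1 score per mouse, the projection on the signature of both diabetic groups together against untreated. This signature was chosen after seeing the data. The test planned before used the signature of the STZ mice, which holds their own chance values, and with it the score differences were −0.057 (exact p = 0.778) for 0.1% and −0.082 (exact p = 0.643) for 0.5% phloridzin.

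The lists, comparisons, tests, thresholds, alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. The rule took, per comparison, (a) the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, or the 3 smallest p where no gene was called, (b) up to 4 called members of each list by smallest p, and (c) a panel of 17 genes, of which 2 were not analysed here. The text names the genes of (a), those of (c) in the first 4 comparisons, and some of (b).

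Genes simulated by adding changes to 200 of 12947 genes, drawn at random, tested the fit in 10 runs. For STZ against untreated, 53.8% of 1.5-fold and 89.6% of 2-fold changes were called, and 8.78% of calls were false; the share of false calls was 16.4% for 0.1% phloridzin against STZ and 14.0% for 0.5%. A list shifted by 0.5 log2 units was called in 10 of 10 runs, with 0 other lists. Genes were simulated independently of each other, whereas the estimated correlation of cholesterol synthesis genes was 0.615. The 0 other lists therefore do not give the rate of false list calls in these data. A planted reversal of 50% was read as 48.6%, with p under 0.05 in 5 of 5 runs, and a planted reversal of 0 gave 0 of 5. The simulated mice of a group did not differ in the size of their response, so these runs do not give the power in the real mice.

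Alternatives were quantile normalization, median centring, no filter or a 60th percentile filter, the mean of probe sets, array weights and a trended robust prior. Others were only the groups compared, a pseudocount of 1, a limit of 1.5-fold, a replicate block and each array left out in turn. A plain two-sided t-test of the 2 groups alone, without moderation of the spread, was also run. Replicate numbers of different groups were those of different mice. Values with the same number correlated between −0.41 and 0.50 after removal of group means, and 13 of 30 pairs of arrays exceeded 0.1. Arrays with unlike numbers were not compared, so this does not decide on pairing. No pairing was assumed, because the numbers belong to different mice.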

Results

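Liver RNA of 20 male BALB/c mice was measured on Affymetrix mouse arrays, with 1 array per mouse. Untreated mice, mice made diabetic with streptozotocin (STZ, a toxin of the insulin-producing beta cell), and STZ mice fed 0.1% or 0.5% phloridzin (a plant inhibitor of sodium-glucose cotransporters) had 5 arrays each. Untreated mice received no injection, so the effects of STZ and of its injection are not separated. The diet lasted 14 days. Per the labels, STZ mice entered the diet groups with blood glucose of 330 to 590 mg/dL. The value of each probe set was a linear signal. Its mean over probe sets after dropping the lowest and highest 2% was 100 on every array, and the median signal per array lay between 11.2 and 17.1. Correlations between arrays of a group lay between 0.9645 and 0.9881 across probe sets, which are not independent replicates. The number of arrays limits the precision: the median 95% interval of a gene's difference was ± 0.30 log2 units (1.23-fold).

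The first comparison, STZ against untreated mice, asks how diabetes changed the liver. Nnmt, which methylates nicotinamide, was 43.4-fold higher in STZ liver (log2 5.44 ± 0.47, SE, n = 5 per group, limma adjusted p = 3.46e-07). Cyp4a14, a fatty acid hydroxylase and target of PPARα, had a mean signal of 3169 ± 2170 (SD) in STZ liver against 14.5 ± 11.2 in untreated liver (adjusted p = 0.000251). Folds are of the signal plus 16. A mean signal of 17.1 or lower, the highest median of an array, is taken as not above background. This limit was read from the data. Where the lower group of a called gene had such a signal, both signals are given and no fold. Among the genes that fell were Hsd3b5, a male-biased steroid dehydrogenase, 24.2-fold lower (−4.60 ± 1.28, adjusted p = 0.0209), and the pseudogene Serpina4-ps1, 17-fold lower (−4.09 ± 0.51, adjusted p = 2.87e-05). With a preset correlation, camera called the lists of p53 targets, female-biased genes and amino acid breakdown higher, and those of male-biased genes, cholesterol synthesis and the unfolded protein response lower, of which the p53 call alone held with an estimated correlation.

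Cplane1 rose to a signal of 558 against 13.6, with 5 of its 6 probe sets in this direction. Its difference was much smaller with the mean of probe sets. Other large rises were those of the steroid hydroxylase Cyp17a1 (16.1-fold), the female-biased cytochrome Cyp2b9 (14.9-fold), the deubiquitinase Usp2 (13.2-fold), the organic anion transporter Slco1a4 (9.77-fold) and the clock repressor Ciart (181 against 4.44). Large falls were those of the fatty acid elongase Elovl3 (16.9-fold), the adipokine gene Serpina12 (14.1-fold, log2 −3.81, or −2.30 with the mean of probe sets), the fatty acid binding protein Fabp5 (8.99-fold), the ribonuclease Rnase2a (9.01 against 190), the thyroid hormone deiodinase Dio1 (13.6 against 136) and 1810008I18Rik (5.09-fold). These 16 genes were picked from called genes for which all 5 STZ arrays lay outside the range of the 5 untreated arrays. STZ replicate 1 had a Cyp4a14 level of 6.02 log2 units against 11.41 to 12.52 in the other 4 STZ mice. Without this array the difference of Cyp4a14 was larger, and the fold was 47.0 for Hsd3b5 and 22.4 for Serpina12. Without STZ replicate 5, Hsd3b5 fell 15.1-fold. Hsd3b5 was not called without STZ replicate 4 or without STZ replicate 5, where its adjusted p was 0.0668 at most.

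**Figure D1:**
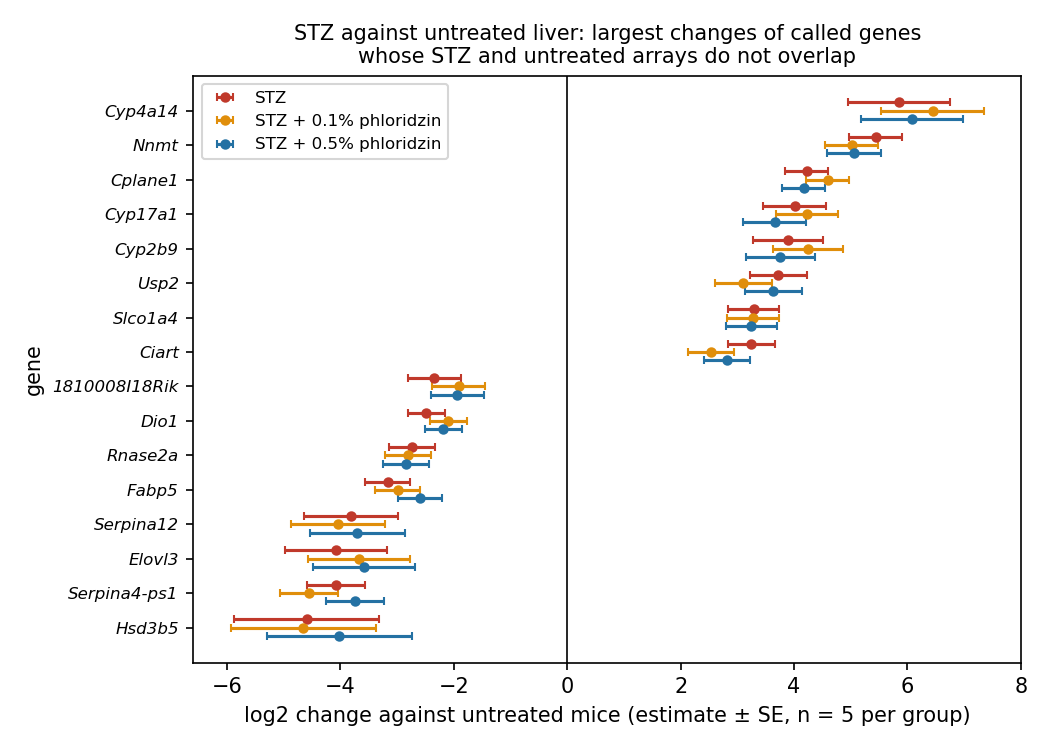
The log2 change against untreated mice (estimate ± SE, n = 5 mice per group) of the 8 largest rises and 8 largest falls in STZ liver, among called genes whose STZ and untreated arrays did not overlap, is drawn for the 3 diabetic groups. Nnmt lay at 5.44 in STZ mice, 5.01 with 0.1% phloridzin and 5.06 with 0.5%, and Hsd3b5 at −4.60, −4.65 and −4.02. Of STZ and untreated liver, the lower signal was not above background for Cyp4a14, Cplane1, Ciart, Rnase2a and Dio1. The drawn changes of these genes depend on the constant added to the signal and are not read as folds.

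In all, limma called 1785 of 12947 genes at an adjusted p under 0.05, 893 higher and 892 lower. Spike-in controls differed too: the bioD signal was 3097 to 3795 on STZ arrays and 3997 to 4794 on untreated arrays, and the cre signal 8881 to 13075 and 12191 to 15462, and this difference was not separated from that of the groups. At least 2-fold changes were seen in 182 genes called higher and 142 called lower. The STZ and untreated arrays did not overlap for 1666 genes, of which 1272 were called. Chance separation of 5 from 5 arrays would give 0.794% of genes, or 103. With each array centred on its median, 1138 genes were called higher and 509 lower (69.1% higher), and with quantile normalization 1005 and 814. Leaving out STZ replicate 5 gave 1171 calls, and array weights gave 2851.

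The p53 targets, which respond to DNA damage, rose: 13 of 19 measured genes were higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 1.04 log2 units and a camera adjusted p of 6.15e-15. This call also held with an estimated correlation, at an adjusted p of 0.00444. Phlda3 rose 6.50-fold (adjusted p = 1.99e-08), Aen, a nuclease of apoptosis, 2.96-fold, and the cyclin Ccng1 2.83-fold, and the receptor gene Eda2r rose to a signal of 59.97 from 4.60. Perp, a desmosome gene named after its values were seen, was the member that fell (−0.52 log2 units). No other list of this comparison kept its camera call with an estimated correlation, so that adjusted p is given for each. Fry, which does not compare a list with other genes, called 23 of 39 lists, which are not the same lists as those of camera. Unlike camera, fry called bile acid synthesis (fry adjusted p = 0.0141) and the pentose phosphate pathway (0.0249). It did not call cholesterol synthesis (0.0521) or fatty acid synthesis (0.125).

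Sex-biased liver genes moved apart. Of 16 female-biased genes, 11 rose and 0 fell (14 adjusted over the list alone; median 1.16; adjusted p = 0.161 with an estimated correlation), among them Acot3 (7.77-fold), Cyp17a1, Cyp2b9 and Cyp3a44 (4.19-fold). Of 17 male-biased genes, 12 fell and 0 rose (16 adjusted over the list alone; median −1.29; adjusted p = 0.200 with an estimated correlation), among them Cyp7b1 (2.84-fold), Ugt2b38 (3.82-fold) and the complement gene C8a (2.32-fold). The growth hormone and IGF axis fell, with 5 of 15 genes lower and 2 higher (7 and 2 adjusted over the list alone; median −0.21; adjusted p = 0.200 with an estimated correlation). Lower members were the repressor Bcl6 (2.44-fold), Egfr (2.59-fold, log2 −1.37, or −0.73 with the mean of probe sets) and the growth hormone receptor Ghr (1.53-fold), while the binding protein gene Igfbp2 rose 2.94-fold. The call of this axis ended without untreated replicate 1 or STZ replicate 2 (adjusted p of 0.0555 at most) and with the mean of probe sets (0.132).

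Genes of gluconeogenesis rose, 5 of 14 higher and 0 lower (6 adjusted over the list alone; median 0.40; adjusted p = 0.171 with an estimated correlation). They included the aminotransferases Got1 (4.56-fold) and Gpt (2.11-fold), the coactivator Ppargc1a (2.76-fold) and the glucose-6-phosphate transporter Slc37a4 (1.64-fold). Amino acid catabolism and the urea cycle rose, 11 of 26 higher and 0 lower (15 adjusted over the list alone; median 0.39; adjusted p = 0.200 with an estimated correlation), with Asl, argininosuccinate lyase, 3.67-fold, Etnppl 2.86-fold, ornithine aminotransferase Oat 2.96-fold and the cationic amino acid transporter Slc7a2 2.86-fold higher. In the tricarboxylic acid cycle 8 of 16 genes rose (9 adjusted over the list alone; median 0.37; adjusted p = 0.200 with an estimated correlation), such as fumarase Fh1 (1.83-fold), and citrate synthase Cs was the 1 gene that fell (1.68-fold). Oxidative phosphorylation shifted by a median of 0.09, with 3 of 46 genes higher (1 adjusted over the list alone; adjusted p = 0.523 with an estimated correlation). Its member Ndufa10 rose 1.36-fold, a call that ended with the mean of probe sets.

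The PPARα targets of fatty acid oxidation and ketogenesis rose, with 12 of 31 genes higher and 1 lower (15 and 2 adjusted over the list alone; median 0.30; adjusted p = 0.267 with an estimated correlation). The fatty acid transporter Cd36 was 4.51-fold and the carnitine transferase Cpt2 1.61-fold higher. The lower member was the hormone gene Fgf21 (−1.96 log2 units), named after its values were seen. Glycolysis and hepatic glucose use had 2 of 10 genes higher and 1 lower (4 and 1 adjusted over the list alone; median 0.21; adjusted p = 0.171 with an estimated correlation). Its camera call ended without untreated replicate 1, 2 or 3 or STZ replicate 1 or 2 (adjusted p of 0.0744 at most) and under 5 other settings, quantile normalization among them (0.107). Sugar transporters had 3 of 10 genes higher (4 adjusted over the list alone; median 0.10; adjusted p = 0.171 with an estimated correlation), with the urate and sugar carrier Slc2a9 1.93-fold higher. This call ended without untreated replicate 1 or 2 or STZ replicate 1 or 2 (adjusted p of 0.0572 at most) and with median centring (0.0528).

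Cholesterol synthesis genes fell, 6 of 19 lower and 0 higher (11 lower and 1 higher adjusted over the list alone; median −0.66; adjusted p = 0.403 with an estimated correlation), with Fdps 3.32-fold (log2 −1.73, or −0.88 with the mean of probe sets) and Hmgcs1 2.57-fold lower. Fatty acid synthesis genes had 4 of 20 lower and 1 higher (9 and 2 adjusted over the list alone; median −0.55; adjusted p = 0.530 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, fell 2.35-fold (log2 −1.23, or −0.63 with the mean of probe sets), and Lpin1, a phosphatidate phosphatase and coactivator, rose 4.18-fold. The camera call of this list ended without untreated replicate 1 or 4 or any of STZ replicates 2 to 5 (adjusted p of 0.115 at most), and STZ replicate 1 had a list mean of 10.34 against 9.43 to 9.56 in the other 4 STZ mice. It also ended with a pseudocount of 1, the 60th percentile filter, the mean of probe sets, or 0.1% phloridzin replicate 4 left out of the spread. Bile acid synthesis and transport was not called by camera, with 7 of 19 genes higher and 4 lower (7 and 6 adjusted over the list alone). Fry called this list higher (fry adjusted p = 0.0141). Its higher members included Akr1d1 (2.05-fold) and the sterol transporter Abcg5 (1.79-fold).

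Xenobiotic metabolism rose, 10 of 21 genes higher and 3 lower (11 and 3 adjusted over the list alone; median 0.51; adjusted p = 0.279 with an estimated correlation), with epoxide hydrolase Ephx1 2.38-fold and the nuclear receptor CAR gene Nr1i3 1.80-fold higher. Oxidative stress defence rose, 10 of 32 higher and 3 lower (11 and 3 adjusted over the list alone; median 0.24; adjusted p = 0.0624 with an estimated correlation), with the glutathione transferase Gsta2 5.94-fold higher. Glucocorticoid receptor targets rose, 7 of 15 higher (8 adjusted over the list alone; median 0.75; adjusted p = 0.279 with an estimated correlation). The metallothionein Mt1, on both lists, rose 13.7-fold (24.8-fold without STZ replicate 1), and Fkbp5 3.72-fold. With the mean of probe sets the log2 difference was 3.02 for Mt1, from 3.78, and 1.31 for Fkbp5, from 1.90. Interferon response genes had 3 of 25 higher, Usp18 (2.58-fold), Gbp2 (57.2 against 16.6) and Gbp3 (2.20-fold) (3 adjusted over the list alone; median 0.25; adjusted p = 0.541 with an estimated correlation). That call ended without STZ replicate 1 (adjusted p = 0.114) and with array weights (0.0720). The unfolded protein response fell, 8 of 25 lower and 0 higher (11 adjusted over the list alone; median −0.33; adjusted p = 0.279 with an estimated correlation). The chaperone Calr was 1.47-fold lower, a call that ended with the mean of probe sets.

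The circadian clock list rose on balance, with 9 of 20 genes higher and 4 lower, and as many adjusted over the list alone (median 0.64; adjusted p = 0.171 with an estimated correlation). The output regulator Dbp was 9.29-fold and Nr1d2 2.70-fold higher, while the activator Npas2 was lower (3.82 against 35.8). Periportal hepatocyte genes rose, 4 of 14 higher and 2 lower (6 and 3 adjusted over the list alone; median 0.27; adjusted p = 0.200 with an estimated correlation), with Cdh1 2.41-fold lower. Pericentral genes were not called by camera, with 6 of 17 higher and 4 lower (7 and 7 adjusted over the list alone), a median of −0.17, a mean of 0.23 and an upward camera direction.

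Among markers of other cell types, MHC class II genes rose, 3 of 7 higher (4 adjusted over the list alone; median 0.61; adjusted p = 0.200 with an estimated correlation): Cd74 (1.99-fold), H2-Eb1 (1.93-fold) and H2-Aa (1.86-fold). B and plasma cell genes fell, 2 of 8 lower (2 adjusted over the list alone; median −0.30; adjusted p = 0.171 with an estimated correlation): Ighm (4.22-fold, log2 −2.08, or −0.41 with the mean of probe sets) and Jchain (1.66-fold). Stellate cell and fibrosis genes fell, 4 of 13 lower (4 adjusted over the list alone; median −0.16; adjusted p = 0.403 with an estimated correlation), with the receptor Pdgfrb 2.15-fold and collagen Col3a1 2.55-fold lower. The stellate call ended without untreated replicate 4 or STZ replicate 2 or 3 (adjusted p of 0.131 at most) and with the mean of probe sets (0.0902).

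The other cell type lists were not called by camera. Their medians and genes called were −0.22 with 1 lower for hepatocytes, 0.13 with 1 higher and 1 lower for Kupffer cells, −0.03 with 1 lower for T and NK cells, −0.27 with 0 for neutrophils, −0.16 with 1 higher for sinusoidal endothelium, 0.19 with 1 lower for cholangiocytes and −0.20 with 1 lower for pancreas. Adjusted over the list alone, 1 hepatocyte gene was higher and 2 lower, and the counts of the other 6 lists were as over all genes. Of the pathway lists not yet named, none was called by camera: glycogen metabolism (4 higher, 2 lower; 5 and 4 adjusted over the list alone), the pentose phosphate pathway (1 lower; 1 higher and 3 lower adjusted over the list alone), insulin signalling (1 and 1 by both adjustments), lipoproteins (2 and 2; 2 and 3 adjusted over the list alone), the acute phase (4 and 3 by both), the proteasome (1 and 2 by both) and the cell cycle (3 and 1; 4 and 1 adjusted over the list alone). Fry called the pentose phosphate list lower (fry adjusted p = 0.0249). Camera, with an adjusted p of 0.0739 for this list, called it lower without STZ replicate 1 (the lowest adjusted p with 1 array left out was 0.0407) and without STZ replicate 4. It also did so under 4 other settings such as quantile normalization (0.0319). The proteasome list was called higher without STZ replicate 3 (0.0453). Lists for erythroid cells and adipocytes (3 measured genes each) and skeletal muscle (2) were too short to test.

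**Figure D2:**
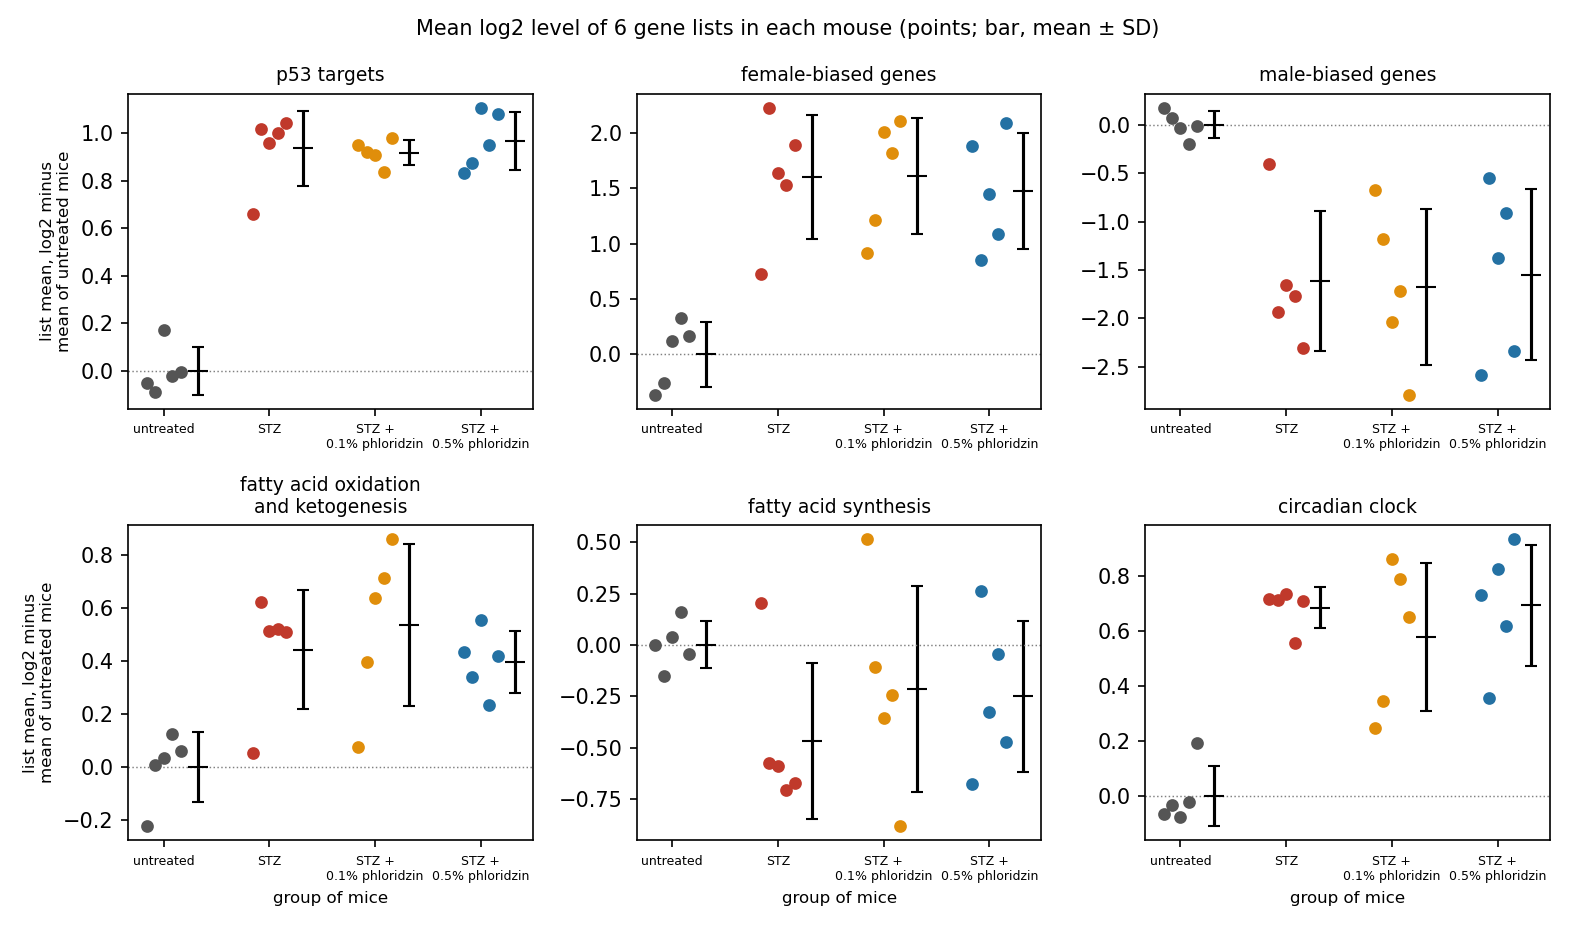
Each point is 1 mouse, with the mean log2 level of 6 gene lists on the vertical axis, given as the difference from the untreated mean, and bars for the mean ± SD of each group. The p53 list lay between 0.66 and 1.11 in the 15 diabetic mice and at or below 0.17 in untreated mice.

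A panel of 15 genes of glucose and lipid metabolism was read in the first 4 comparisons. The bile acid enzyme Cyp7a1 rose 8.38-fold in STZ liver (3.07 ± 0.49, adjusted p = 0.000354), Slc2a2, the hepatic glucose transporter, 1.29-fold (adjusted p = 0.00273) and Igfbp1, an insulin-repressed gene, 3.35-fold (adjusted p = 0.0392). The desaturase Scd1 fell 4.38-fold (adjusted p = 0.0255). The fatty acid synthase Fasn (−1.55 ± 0.57, adjusted p = 0.0761), the gluconeogenic genes G6pc (0.49 ± 0.24, adjusted p = 0.191) and Pck1 (0.41 ± 0.18, adjusted p = 0.135), the transporters targeted by phloridzin, Slc5a1 (−0.16, with a signal of 13.3 against 16.3, not above background) and Slc5a2 (0.05, 25.6 against 24.3), and Srebf1 (−0.18), Igf1 (−0.02), Pdk4 (−0.30) and Txnip (0.30) did not pass. Igfbp1 was not called with 8 of the 10 arrays left out singly, all but untreated replicate 3 and STZ replicate 1 (adjusted p of 0.105 at most), without the filter, or with a trended robust prior. Scd1 was not called without untreated replicate 3 or STZ replicate 3, 4 or 5 (adjusted p of 0.0765 at most). Fasn was called without STZ replicate 1 (−1.90, adjusted p = 0.0294), with array weights and with these groups fitted alone. Pck1 was called with quantile normalization, the mean of probe sets and these groups alone.

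The next comparisons ask whether a phloridzin diet changed the diabetic liver. Against STZ mice on the plain diet, no gene passed with 0.1% phloridzin: limma called 0 of 12947 genes, 685 had an unadjusted p under 0.05 where 647 would by chance, and the smallest adjusted p was 0.921. Cyp7a1 lay at −1.14 log2 units (95% interval −2.16 to −0.12), Scd1 at 0.93 (−0.35 to 2.22), Fasn at 0.89 (−0.30 to 2.08), Cyp4a14 at 0.60 (−1.28 to 2.47) and Igfbp1 at 0.14 (−1.01 to 1.28). The gluconeogenic genes G6pc (−0.10) and Pck1 (0.14), the glucose transporters Slc5a1 (0.09), Slc5a2 (0.32) and Slc2a2 (−0.03), and Srebf1 (0.03), Igf1 (0.14), Pdk4 (−0.09), Txnip (0.08) and Ppargc1a (−0.26) did not pass either. The 3 genes with the smallest p, Camkk2 (0.46), Zfp931 (−0.66) and Kdm2b (−0.56), did not pass. Without moderation of the spread 0 genes were called, and 88 genes had groups without overlap, where chance gives 103 (0.794%).

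Camera called 10 of 39 lists between these groups, 9 higher and 1 lower, but 0 with an estimated correlation (lowest adjusted p = 0.335) and 0 with fry. The highest shift was in hepatocyte genes (median 0.38, adjusted p = 0.335 with an estimated correlation), with 0 of 11 genes called (2 higher adjusted over the list alone). Other lists called higher were fatty acid synthesis (median 0.24), xenobiotic metabolism (0.21), pericentral genes (0.19), the acute phase (0.18), lipoproteins (0.14), amino acid catabolism (0.13), oxidative stress defence (0.09) and oxidative phosphorylation (0.08), and the unfolded protein response was called lower (−0.13). None of their genes was called, over all genes or adjusted over the list alone. The 190 brightest genes outside the hepatocyte list had a median of 0.20 in this comparison, where all genes had −0.004. After quantile normalization 2 lists were called, fatty acid synthesis and the unfolded protein response, and the medians of amino acid catabolism (−0.03) and oxidative phosphorylation (−0.008) changed sign. Of the 10 calls 7 ended with at least 1 array left out. Replicate 4 of 0.1% phloridzin was the array with the highest spike-in signals after scaling. Without it, the calls of xenobiotic metabolism (median 0.073, adjusted p = 0.0942) and amino acid catabolism (0.069, adjusted p = 0.107) ended, and the hepatocyte median was 0.19. Without STZ replicate 1 these 2 calls and those of oxidative stress defence, pericentral genes and the unfolded protein response ended, and 5 lists were called. Calls also ended for fatty acid synthesis without replicate 1 of 0.1% phloridzin (adjusted p = 0.344), the unfolded protein response without its replicate 2 or 5 (0.361 at most), xenobiotic metabolism without its replicate 3 and oxidative phosphorylation without its replicate 5 (0.0813).

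At 0.5% phloridzin limma again called 0 genes against STZ mice, with 622 at an unadjusted p under 0.05 and a smallest adjusted p of 0.859. Scd1 lay at 1.06 log2 units (95% interval −0.23 to 2.34), Fasn at 0.56 (−0.62 to 1.75), Cyp7a1 at −0.41 (−1.43 to 0.61), Igfbp1 at 0.27 (−0.88 to 1.42) and Cyp4a14 at 0.23 (−1.65 to 2.10). Nor did G6pc (−0.05), Pck1 (−0.12), Slc5a1 (−0.16), Slc5a2 (0.21), Slc2a2 (0.04), Srebf1 (0.17), Igf1 (−0.05), Pdk4 (0.27), Txnip (−0.04) or Ppargc1a (−0.03) pass. The smallest p were those of the spindle gene Knstrn (0.64), Gtpbp8 (−0.55) and the repressor Bcl6 (−1.03), which did not pass. Without moderation of the spread 0 genes were called, and 109 had groups without overlap, beside 103 by chance (0.794%). In data simulated for this comparison, 88.0% of genes changed 2-fold and 57.6% of those changed 1.5-fold were recovered (90.0% and 54.0% for 0.1% phloridzin). The changed genes were drawn at random, so these shares do not hold for more variable genes. Scd1, for one, was not called at 1.06 log2 units. Camera called 6 lists, cell cycle genes higher (median 0.20) and PPARα targets (−0.09), the unfolded protein response (−0.12), amino acid catabolism (−0.08), oxidative phosphorylation (−0.04) and the proteasome (−0.06) lower. With an estimated correlation (lowest adjusted p = 0.911) and with fry, 0 lists were called. None of their genes was called, over all genes or adjusted over the list alone. Without STZ replicate 4, STZ replicate 5 or 0.5% phloridzin replicate 2, 1 list was called, and without 0.5% phloridzin replicate 4, 3 lists were. Each of the 6 calls ended with at least 1 array left out: the unfolded protein response without STZ replicate 1 (adjusted p = 0.0657), PPARα targets without STZ replicate 2, 3, 4 or 5 or replicate 2 or 4 of 0.5% phloridzin (0.40 at most), amino acid catabolism and oxidative phosphorylation without STZ replicate 4 or 5 or those same 2 (0.451 and 0.570 at most), the proteasome without STZ replicate 4 or 5 or replicate 2 of 0.5% phloridzin (0.253 at most), and the cell cycle without STZ replicate 3, 4 or 5 or replicate 1 or 2 of 0.5% phloridzin (0.139 at most).

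For the dose comparison, 0.5% against 0.1% phloridzin, limma called 0 genes, with 840 at an unadjusted p under 0.05 and a smallest adjusted p of 0.607. Without moderation of the spread 0 genes were called, and 104 did not overlap, beside 103 by chance (0.794%). The smallest p, none of which passed, were those of Lin54, a regulator of cell cycle genes (0.52), Ccdc82 (0.54) and Afap1l2 (0.75). The panel genes lay between −0.37 (Cyp4a14) and 0.73 (Cyp7a1), with Scd1 at 0.13, Fasn at −0.33, Igfbp1 at 0.13, G6pc at 0.05, Pck1 at −0.26, Slc5a1 at −0.25, Slc5a2 at −0.12, Slc2a2 at 0.08, Srebf1 at 0.13, Igf1 at −0.18, Pdk4 at 0.36, Txnip at −0.12 and Ppargc1a at 0.23, and none passed. Camera called 13 lists. Cell cycle genes were higher (median 0.18), and lower lists were hepatocyte genes (−0.30), amino acid catabolism (−0.23), lipoproteins (−0.19), oxidative phosphorylation (−0.15), PPARα targets (−0.14), xenobiotic metabolism (−0.14), the acute phase (−0.13), oxidative stress defence (−0.12), pericentral (−0.11) and periportal genes (−0.09), bile acids (−0.07) and the proteasome (−0.04). None held with an estimated correlation (lowest adjusted p = 0.264) or with fry, and none of their genes was called, over all genes or adjusted over the list alone. The 190 brightest genes outside the hepatocyte list had a median of −0.18. After quantile normalization 4 lists were called, and 5 of the 13 calls ended with at least 1 array left out. Each of these 5 ended without replicate 2 of 0.5% phloridzin. Bile acids also ended without its replicate 3 or replicate 3, 4 or 5 of 0.1% phloridzin (adjusted p of 0.145 at most), xenobiotic metabolism without replicate 4 of 0.5% or 3 or 4 of 0.1% (0.268), the proteasome without replicate 1 or 5 of 0.1% (0.151), pericentral genes without replicate 4 of 0.1% (0.0804), and periportal genes without replicate 3 or 4 of 0.5% or 3 or 5 of 0.1% (0.145).

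Both phloridzin groups differed from untreated mice in genes that also stood out in STZ mice. With 0.1% phloridzin 2168 genes were called, 1005 higher and 1163 lower, and with 0.5%, 1646 genes, 846 and 800. Nnmt was 32.3-fold and 33.3-fold higher, Cyp2b9 19-fold and 13.6-fold, Cyp17a1 18.8-fold and 12.6-fold, and the metallothioneins Mt1 19.8-fold and 23.1-fold and Mt2 15.3-fold and 24.6-fold. Higher from untreated signals not above background were Cyp4a14 (signals of 3242 and 2529 against 14.5), Cplane1 (728 and 586 against 13.6) and the estrogen sulfotransferase Sult1e1 (391 and 411 against 2.61). Lower in both were Hsd3b5 (25.2-fold and 16.3-fold), Serpina4-ps1 (23.5-fold and 13.4-fold), Serpina12 (16.5-fold and 13.0-fold), Elovl3 (12.7-fold and 12.0-fold), Fabp5 (7.93-fold and 6.05-fold) and Rnase2a (6.00 and 5.61 against 190). Among the 8 largest falls of called genes without overlap were also Cyp4a12a (6.64-fold) and Slco1a1 (6.25-fold) with 0.1% phloridzin, and G0s2 (6.78-fold) and Serpina9 (9.51 against 106) with 0.5%. With the mean of probe sets the difference of Cplane1 was much smaller in both groups. The log2 differences were then 3.47 and 3.75 for Mt1 (from 4.30 and 4.53) and −2.38 and −2.22 for Serpina12 (from −4.04 and −3.70). Several of these falls depended on 1 array. Without replicate 1 of 0.1% phloridzin the fold was 46.2 for Hsd3b5 and 19.5 for Elovl3, and without its replicate 5 it was 14.3 for Hsd3b5, 8.27 for Elovl3 and 4.08 for Slco1a1. Without replicate 1 of 0.5% phloridzin the fold was 8.54 for Hsd3b5 and 7.25 for Elovl3, and without its replicate 2 it was 27.5 for Hsd3b5, 19.3 for Elovl3 and 20.1 for Serpina12. Hsd3b5 lost its call without replicate 5 of 0.1% phloridzin (adjusted p = 0.0558), and at 0.5% without any untreated replicate or without replicate 1, 3 or 5 of that group (adjusted p of 0.140 at most). Cyp4a12a was not called without any untreated replicate or without replicate 3, 4 or 5 of 0.1% phloridzin (0.120 at most), nor was Slco1a1 without untreated replicate 1 or 2 or those 3 replicates (0.0911 at most). Genes called with 0.5% phloridzin numbered 1084 without untreated replicate 1, 944 without replicate 1 of that group and 980 without its replicate 5. Spike-in signals of the 0.5% arrays also lay below those of untreated arrays. The bioD signal was 3200 to 3672 against 3997 to 4794, and the cre signal 10418 to 11591 against 12191 to 15462. This difference was not separated from that of the groups. On 0.1% phloridzin arrays the bioD signal was 3173 to 14067 and overlapped the untreated range.

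STZ and 0.1% phloridzin mice, each against the untreated mice, shared 682 genes higher and 620 lower, and 0 in opposite directions. Independent lists of these sizes would share 69.3 and 80.1. Changes correlated at 0.914 across genes, which are not independent replicates, beside 0.391 for simulated unchanged groups against the same controls, and their covariance was 0.149 beside 0.0108. With untreated mice split between both comparisons the correlation was 0.794, the covariance 0.139 and the overlap 209 higher and 131 lower. Each comparison then had fewer untreated arrays, and a mean of 725 genes were called for STZ and 958 for 0.1% phloridzin. The smaller overlap therefore does not measure the part due to shared controls. For STZ and 0.5% phloridzin the shared genes were 620 higher and 517 lower (58.4 and 55.1 for independent lists), the correlation 0.916 (0.398 simulated) and the covariance 0.146 (0.0107 simulated). Split controls gave 0.792, 0.135, 177 higher and 97 lower, with a mean of 725 genes called for STZ and 615 for 0.5% phloridzin. Splitting the controls does not remove a difference of all untreated arrays from both other groups, such as that of the spike-in signals. The changes of both phloridzin groups against the shared STZ mice correlated at 0.459, beside 0.460 simulated, with a covariance of 0.0126 beside 0.0152. Splitting the STZ mice gave a correlation of −0.048 and a covariance of −0.00265.

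The last comparison asks whether phloridzin turned the diabetic change of the liver back. Genes called between STZ and untreated mice had moved, with 0.1% phloridzin, by a median of 0.00013 log2 units along the STZ direction, where a value under 0 means a return and the STZ change itself was 0.81. The STZ arrays used for the 2 contrasts were disjoint in each of 20 splits, whose values ran from −0.10 to 0.11, with 957 genes per split. With 0.5% phloridzin the median was −0.03 (splits −0.12 to 0.10, 1003 genes). On a score set to 0 at the untreated mean and 1 at the mean of the diabetic mice compared, STZ mice had 0.997 ± 0.212 (SD, n = 5) and 0.1% phloridzin mice 1.00 ± 0.289, a difference of 0.007 (95% interval −0.41 to 0.39) with a two-sided exact permutation p of 0.960. For 0.5% phloridzin the scores were 1.01 ± 0.224 and 0.991 ± 0.330, a difference of −0.017 (−0.46 to 0.42) with an exact permutation p of 0.921. Adjusted over the 2 tests by Benjamini and Hochberg, both p were 0.960, and the smallest p that the splits of 10 mice can give is 0.00794. The signature of this score was chosen after seeing the data. With the planned one, that of the STZ mice alone, the differences were −0.057 (exact p = 0.778) and −0.082 (exact p = 0.643). Neither sign was stable. The 0.1% value was −0.014 with median centring, and with 1 array left out it ran from −0.069 (STZ replicate 1) to 0.073 (replicate 1 of that group) and was under 0 without any untreated replicate but 4, without STZ replicate 1 or 4 and without replicate 3, 4 or 5 of that group. The 0.5% value ran from −0.095 (STZ replicate 1) to 0.044 (replicate 2 of that group). With all 5 STZ arrays in both contrasts, a form that lies under 0 for relabelled mice (−0.042 and −0.045), the values were −0.048 and −0.079.

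**Figure D3:**
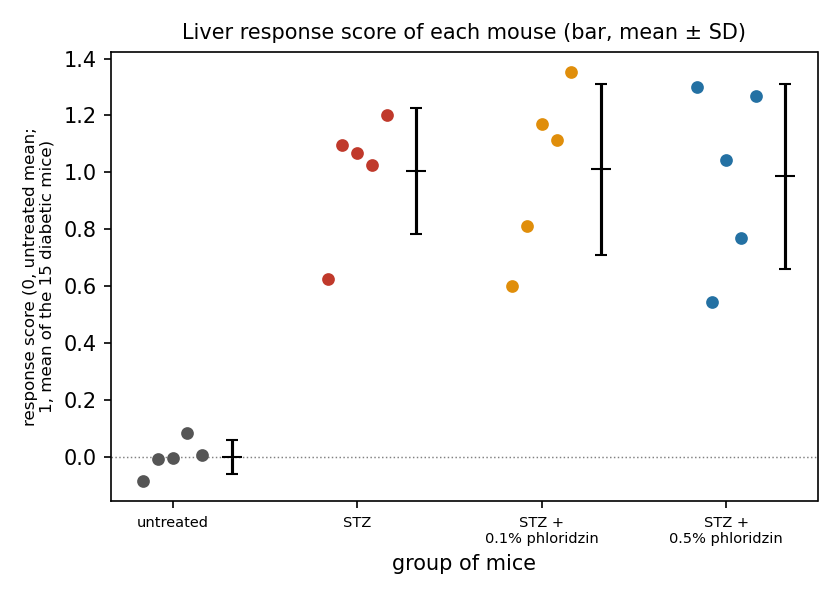
Each point is the liver response score of 1 mouse (vertical axis, 0 at the untreated mean and 1 at the mean of the 15 diabetic mice), with bars for the mean ± SD of each group (n = 5). Scores ran from 0.626 to 1.20 in STZ mice, from 0.602 to 1.35 with 0.1% phloridzin and from 0.543 to 1.30 with 0.5%.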

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

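The tests of the hepatocyte and p53 patterns, and the division of clock genes into 2 phases, were chosen only after the results were seen. Of 248 checks for a mouse or array far from the other 4 of its group, 22 passed the limit, where chance gives about 12.4 (1 in 20).

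After scaling, the array of 0.1% phloridzin replicate 4 had higher mean, highest and spike-in signals than the other 4 of its group. Its mean signal was 224.16 against 185 to 195, and its highest signal 37014 against 14117 to 19414. Its cre spike-in control was 33369 against 10401 to 14732, and its bioB spike-in control 1252.9 against 217 to 308. All arrays had been scaled to the same trimmed mean, so these values do not show whether this array was brighter before scaling. Its mean log2 level of hepatocyte genes was 14.18 against 13.18 to 13.46. The hepatocyte list was the list that rose most with 0.1% phloridzin against STZ (median 0.38). With an estimated correlation the list was not called even with all arrays (adjusted p = 0.335). Without that array the median fell to 0.19 from 0.38, and the camera adjusted p at the preset correlation was 0.000135, which argues against this array as the whole cause of the call at that setting. Quantile normalization brought the median from 0.38 to 0.01 and ended the call (camera adjusted p = 0.64). It makes the highest signals alike across arrays, and hepatocyte genes are among the highest. This outcome was thus nearly fixed in advance and does not decide between a shift of bright genes and a change of this list. Lists matched on mean level moved by a median of 0.26, with 0.97% of them as high as the hepatocyte list. From the matched lists, a shift of the brightest genes as a whole is a candidate explanation for most of the change. An action of the diet cannot be told apart from it, since each array has its own scale and the list median for 0.5% phloridzin against STZ was 0.051.

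Clock genes differed between STZ and untreated mice by phase. Of 10 genes that peak early, 6 were higher (median 1.13), and of 5 that peak late, 4 were lower (median −1.37). The others were not called. Of these, early Nr1d1 (−0.26) and Bhlhe41 (−0.25) and late Cry1 (0.67) lay against their phase, and early Per2 (0.60) and Hlf (0.15) lay with it. Over the 15 diabetic mice, with groups removed, the clock score and the response score had a Pearson r of 0.415 (permutation p = 0.183; adjusted over 2 relations 0.183) and a Spearman rho of 0.461 (permutation p = 0.134). Without the 2 mice farthest from the median r was 0.056 (permutation p = 0.867). A killing time shared by each whole group and the degree of each mouse's diabetic response may both give the shift and cannot be told apart, since killing times are not given in the labels and the relation within groups did not pass.

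The p53 list was higher in each of the 15 diabetic mice than in any untreated mouse. These mice lay 0.66 to 1.11 log2 units above the untreated mean and the highest untreated mouse 0.17 above it, with STZ replicate 1 below the other 4 STZ mice. Its spread relative to its shift, 0.126, was the lowest of the 23 lists called. After quantile normalization the adjusted p with an estimated correlation was 0.0116, which argues against scaling between arrays. Its relative shift had a slope of 0.183 on the relative response score (95% interval −0.079 to 0.445), where a shift in proportion to each mouse's metabolic response would have a slope of 1. This does not decide, since the list was singled out for its low spread, from which a low slope follows. The p53 and response scores had an r of 0.420 (permutation p = 0.120; adjusted 0.183) and a rho of 0.300 (permutation p = 0.320), and an r of 0.465 (permutation p = 0.117) without the 2 farthest mice. Cells of another type cannot be told apart, since the highest median of another cell type list, 0.61 for MHC class II, lies above the bound of 0.52. Streptozotocin alkylates DNA, and a lasting response of liver cells to the toxin itself may explain the list, but no group received STZ without diabetes, so this was not tested.

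STZ replicate 1 differed from the other 4 STZ mice in 9 measures. Its list means were 10.34 for fatty acid synthesis (others 9.43 to 9.56), 9.77 for PPARα targets (10.23 to 10.34), 7.48 for p53 targets (7.78 to 7.86) and 9.16 for glucocorticoid receptor targets (10.13 to 10.42). Its log2 levels were 10.51 for Srebf1 (9.25 to 9.61), 10.21 for Fasn (8.26 to 8.63), 9.74 for Igfbp1 (11.89 to 12.49), 6.02 for Cyp4a14 (11.41 to 12.52) and 6.33 for Ppargc1a (7.36 to 7.72). Its response score was also the lowest of the STZ mice, 0.63 against 1.02 to 1.20. Low scores were not particular to this mouse. Replicate 1 of 0.1% phloridzin had 0.60 (others 0.81 to 1.35) and replicate 2 of 0.5% had 0.54 (others 0.77 to 1.30). No explanation was tested.

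Other single mice lay far from their group. Untreated replicate 5 had a Gapdh 3′ to 5′ ratio of 1.0745 (others 0.698 to 0.772) and a clock mean of 7.02 (6.76 to 6.81). STZ replicate 4 had a clock mean of 7.39 (7.54 to 7.57) and STZ replicate 3 a cholangiocyte mean of 4.62 (4.89 to 4.98). Untreated replicate 1 had an MHC class II mean of 6.23 (6.46 to 6.52). With 0.1% phloridzin, replicate 1 had a periportal mean of 10.17 (10.35 to 10.41) and a Txnip level of 9.10 (9.69 to 9.85), and with 0.5%, replicate 1 had an Slc5a1 level of 4.13 (4.74 to 4.87).

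Camera with the preset correlation called 13 lists between the doses, with medians of −0.14 for PPARα targets, −0.068 for bile acids, −0.188 for lipoproteins, −0.137 for xenobiotic metabolism, −0.121 for oxidative stress defence, −0.133 for the acute phase, −0.232 for amino acid catabolism, −0.145 for oxidative phosphorylation, −0.044 for the proteasome, 0.179 for the cell cycle, −0.107 for pericentral genes, −0.087 for periportal genes and −0.301 for hepatocyte genes. None held with an estimated correlation. Among the probe sets without a single listed gene, which the comparisons do not use, 4006 passed the filter on signal, and 199 of these were called between STZ and untreated mice, 107 higher and 92 lower.

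Other splits of the 10 mice of each comparison into groups of 5 were counted, 100 of 126 possible, the real one included. For STZ against untreated, chance can be excluded for the number of genes (1785, at most 32 in another split, 1 of 100 with as many). The same holds for 0.1% phloridzin against untreated (1 of 100, with 2168 and 541 genes) and for 0.5% (1 of 100, with 1646 and 254). For the 23 lists of STZ against untreated, 1 of 100 splits gave as many, but another split gave 21. That margin is narrow and does not show which of the 23 lists exceed chance. For the 0 genes of the other comparisons, 100 of 100 splits gave as many, with up to 27 genes for 0.1% phloridzin against STZ, 37 for 0.5% against STZ and 962 between the doses. A count of 0 is always reached, so these say nothing about chance. The 962 genes, and 898 in another split, point to a structure among the phloridzin mice, which was not tested further. Response scores ran from 0.602 to 1.353 with 0.1% phloridzin and from 0.543 to 1.301 with 0.5%. Whether this spread gives the structure was not tested. Chance cannot be excluded for the lists of 0.1% phloridzin against STZ (52 of 100 splits gave 10 or more, at most 24), of 0.5% against STZ (60 gave 6 or more, at most 19) and between the doses (30 gave 13 or more, at most 24).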

How the results depend on the processing

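Fits with all 4 groups for the reversal, the signature of both diabetic groups in its exact test, in place of the planned one of the STZ mice, and fits without 0.1% phloridzin replicate 4 in the spread were chosen after seeing the data. With a limit of 1.5-fold, 878 genes were called for STZ, 942 for 0.1% and 835 for 0.5% phloridzin against untreated, fewer by construction. Array weights gave 2851 for STZ and 2610 for 0.5% phloridzin, and the cause was not tested. Each comparison between diabetic groups had 0 genes under each setting. With a replicate block, 1923 genes were called for STZ. Lists called with an estimated correlation were 1 for STZ and 0 in the other 3 comparisons, and fry called 23 for STZ and 0 in the other 3. Quantile normalization left 2 lists for 0.1% phloridzin against STZ and 4 between the doses. The reversal by 0.1% phloridzin was 0.00013 and changed sign, to −0.0013 with quantile normalization and with no filter, −0.014 with median centring and −0.003 with the mean of probe sets. With all 5 STZ arrays in both contrasts it was −0.048 for 0.1% and −0.079 for 0.5%, where relabelled mice gave −0.042 and −0.045, so a value under 0 is expected there with no change. With all 4 groups the 0.1% value was 0.0053. With 1 array left out, genes called ranged from 1171 to 1991 for STZ, 1492 to 2620 for 0.1% and 944 to 2188 for 0.5% phloridzin against untreated, and lists from 18 to 23 for STZ, 5 to 11 for 0.1% against STZ, 1 to 8 for 0.5% against STZ and 9 to 16 between the doses. The reversal ranged from −0.069 to 0.073 for 0.1% and −0.095 to 0.044 for 0.5%. Of 2483 values for the 131 named genes called with STZ, 2318 kept their call, 165 lost it and 0 reversed. Array weights and a pseudocount of 1 were not run for the reversal, and its groups alone were already the fit. Signal near background limits weakly expressed genes, since the filter lay at a signal of about 8.48.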
